A study of Homo sapiens with 16 samples.

How the data were processed

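RNA sequencing libraries came from ECC-1 endometrial and T-47D breast cancer cells. Per the labels, cells were kept for 5 days in phenol red-free RPMI-1640 with 10% charcoal-stripped serum in 100 mm dishes, a medium low in hormones. They then received 0.02% DMSO, 10 nM 17β-estradiol, 100 nM BPA or 100 nM genistein for 8 h. There are 2 libraries for each of the 8 combinations of line and treatment, 16 in all, made from polyadenylated RNA with a transposase method that keeps no strand, so antisense or overlapping genes cannot be told apart. The labels do not say whether the replicates are separate cultures, so the p-values measure the spread between these samples only.

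The authors deposited 1 table per library with RPKM values (reads per kilobase of transcript and M reads), 1 for each of 32062 RefSeq transcripts. Per the submitters' processing notes reads were aligned with Bowtie to hg19, with no versions given. How reads were counted, and how reads matching several places were handled, is not given in the sources used here. The annotation at hand is on another genome build, so coordinates are not given here. Estrogen receptor binding data, which the series title concerns, were not analysed here.

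The files hold no counts. Depth was estimated from the steps between low RPKM values, since the RPKM of a transcript rises in steps of 1 read, and came to 17.24 to 29.24 M reads per library. At these depths, 60.5 to 63.3% of the values under 10 reads lay within 0.1 read of a whole number, where 20% would by chance. A transcript of 2 kb at 1 RPKM then rests on 34.5 to 58.5 reads. No 2 libraries were identical.

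The 32062 rows cover 21453 gene symbols. For the 5983 symbols with several rows, the transcript with the highest mean was used. Each library was divided by a scale factor, the median ratio to the geometric mean over 7547 genes with at least 5 RPKM in all libraries (0.938 to 1.054). Genes with at least 1 RPKM in at least 2 libraries, 13827 in all, were tested on log2(scaled RPKM + 0.5). The pseudocount of 0.5 makes log2 changes and folds of low genes smaller than the ratio of their means.

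A single limma model with 8 group means was fitted over the 16 libraries (8 residual degrees of freedom, prior degrees of freedom 6.9), with eBayes and a mean-variance trend. Contrasts were each treatment against DMSO, each pair of treatments, each interaction between line and treatment, and T-47D against ECC-1 in DMSO. P-values were adjusted by Benjamini-Hochberg within each contrast, with a threshold of 0.05. The median 95% interval reached 0.33 on the log2 scale to either side for treatment contrasts and 0.47 for interactions. No group has more than 2 libraries, so permutation of labels within a contrast was not used.

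Named genes follow a rule. Among genes past the threshold with a mean of at least 1 scaled RPKM, whose treated libraries both lie outside the range of both control libraries (not asked of interactions), the 12 largest rises and falls with estradiol and the 8 largest in other contrasts were taken. A panel of 10 genes (GREB1, TFF1, PGR, PDZK1, CXCL12, MYC, CCND1, IGFBP4, ESR1, CYP1A1), up to 4 members of each list and the marker and receptor lists were added. From these the text mostly names genes whose calls held in all alternatives in which single genes were followed (scaling, pseudocounts, the block, trend removal and left-out libraries). The number of alternatives that a call survived was seen when that choice was made.

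There were 24 gene lists, of which 22 had at least 3 members among the tested genes, giving 132 list tests: estrogen-induced and estrogen-repressed genes of breast cancer cells, estrogen-linked genes of the endometrium, G1/S, G2/M, immediate early, ribosome biogenesis, ribosomal protein and heat shock genes, replication-dependent histones, targets of the aryl hydrocarbon receptor, of NRF2 and of the glucocorticoid and progesterone receptors, unfolded protein and amino acid stress, sterol synthesis and interferon-induced genes, apoptosis regulators, steroid receptors and cofactors, and markers of luminal breast, endometrium, fibroblasts, leukocytes and endothelium, and 1 further list that is left out of the text. That list counts among the tests and holds 2 of the 36 list calls, both of which ended with an estimated correlation. An older symbol of that list was not matched. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Some genes stand in several lists, MYC among them.

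The size of a compound response relative to estradiol used the genes changed by estradiol in the line. Its reference without a response was simulated in 50 draws with shared DMSO libraries. It was first drawn with 1 pooled spread, which gave 0.0268 for BPA in ECC-1 (highest 0.0623) and 0.0303 in T-47D (highest 0.0483, with 56.6% of genes in the same direction and 60.8% at most). For genistein it gave 0.0258 (highest 0.0544) and 0.0293 (highest 0.0695). After these values were seen it was changed to each group's own spread, which the text reports.

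The contrasts, lists, threshold, naming rule and first set of alternatives were chosen before the data were examined. That set held no scaling, quantile normalization, pseudocounts of 0.1 and 1, no filter and a mean of at least 5 RPKM, the replicate number as a block, array weights, robust eBayes, a fit on 1 cell line (4 residual degrees of freedom), sums over transcripts, estimated correlation, fry, separate DMSO libraries for the relative size, and each library left out in turn. Leaving 1 library out leaves a group with a single library, which the model assumes to vary like the others. Removal of transcript length and GC trends (13010 genes, 94.1% of those tested, had both), the same with the block, omission of both first estradiol libraries and the estimated correlation for the sets of the other line were chosen after seeing the data.

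The whole procedure was tested on simulated data in 10 draws with the measured levels and spreads and with 200 genes changed per comparison. Recovery depends on that number, since adjustment is stricter where few genes change. For estradiol in ECC-1, 17.8%, 89.0%, 99.4% and 99.8% of genes changed by a log2 of 0.5, 1, 1.5 and 2 were recovered, with 18.5 false calls per draw, above the nominal rate. For BPA in T-47D these were 16.8%, 90.4%, 99.0% and 99.8%, with 3.2 false calls per draw. A simulated relative size of 0.4 was returned as 0.395 (0.384 to 0.41). A changed list was called in 10 of 10 draws, and 0 of 210 tests of unchanged lists passed camera. The noise of each gene was drawn independently, so these list results do not cover lists whose genes vary together. Ribosomal protein genes, for example, had an estimated correlation of 0.77. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, models were fitted in R 4.3.3 with limma 3.58.1, and figures were drawn with matplotlib 3.10.9.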

Results

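The comparisons below ask which transcripts changed after 8 h of 17β-estradiol, bisphenol A (BPA, a plastics monomer) or genistein (a soy isoflavone). ECC-1 endometrial and T-47D breast cancer cells both carry estrogen receptor alpha, the product of ESR1. BPA and genistein were given at 100 nM each and estradiol at 10 nM, so comparisons with estradiol are across doses. The control was DMSO at 0.02%. Levels are scaled RPKM, shown as mean ± SD with n = 2 libraries in each of the 8 groups. Changes are log2 differences with their standard error (SE) or 95% interval, from 1 limma fit over all 16 libraries and 13827 genes. A gene counts as changed at an adjusted p under 0.05. The fit assumes 1 spread for all groups, though estradiol groups varied more, and simulated ECC-1 estradiol calls exceeded the nominal error rate. Unless stated, both treated libraries of each named changed gene lay outside the range of both control libraries on the same side.

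The control libraries separated the lines by the marker genes of their tissues. In T-47D, the luminal breast transcription factor genes GATA3 (300.2 ± 50.3 scaled RPKM) and FOXA1 (170.8 ± 0.257), the ETS factor gene SPDEF (205.8 ± 8.38) and TRPS1 (165.5 ± 30.5) were abundant, against 0.0184 ± 0.00426, 3.06 ± 0.0745, 0.122 ± 0.0743 and 2.54 ± 0.173 in ECC-1. The secreted protein gene PIP stood at 220.2 ± 61.2 in T-47D and was listed at 0 in both ECC-1 control libraries. In ECC-1, PAX8, a marker of Mullerian epithelium, stood at 91.0 ± 6.67 against 0.0242 ± 0.00649 in T-47D (log2 difference -7.45, SE 0.158, adjusted p = 4.15e-15). The homeobox gene MSX1 stood at 189.1 ± 3.6 against 0.518 ± 0.0351, and EMX2 at 16.1 ± 1.26 against 0.00685 ± 0.00969. SOX17 (27.1 ± 3.21) and HOXA10 (13.9 ± 0.266) were listed at 0 in both T-47D control libraries. Of the 13827 genes, 5469 were higher and 5135 lower in T-47D than in ECC-1.

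Receptor and cofactor transcripts differed between the lines as well. ESR1 stood at 31.4 ± 4.67 in T-47D and 21.6 ± 2.93 in ECC-1, a log2 difference of 0.53 (95% interval 0.15 to 0.90, adjusted p = 0.0131). That call ended without the second ECC-1 DMSO library (0.39) or without the second T-47D DMSO library (0.38). The progesterone receptor gene PGR stood at 63.4 ± 7.15 in T-47D and 0.071 ± 0.0327 in ECC-1. The coactivator gene NCOA3 was higher in T-47D by a log2 difference of 2.10 (SE 0.144, adjusted p = 2.85e-09), and NCOA2 by 1.69 (SE 0.202). ETV4, which encodes an ETS factor, was lower in T-47D, at 0.0856 ± 0.0229 against 8.53 ± 1.09. The glucocorticoid receptor gene NR3C1 was lower by a log2 difference of -0.55 (adjusted p = 0.00712), while GPER (-0.01) and ESRRA (0.26) did not pass the test. ESR2, the gene of estrogen receptor beta, stood at 0.177 ± 0.0992 in T-47D and 0.256 ± 0.125 in ECC-1, too low to be tested.

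Replicate libraries were close in most groups, and the estradiol groups were the exception. The SD over genes of the log2 difference between the 2 libraries was 0.343 for estradiol in ECC-1 and 0.411 in T-47D, against 0.17 to 0.242 in the other 6 groups. The first estradiol library stood apart in each line, with a median correlation across genes with the other libraries of its line of 0.9873 in ECC-1 and 0.9801 in T-47D. The other 14 libraries lay between 0.9893 and 0.9966.

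**Figure D1:**
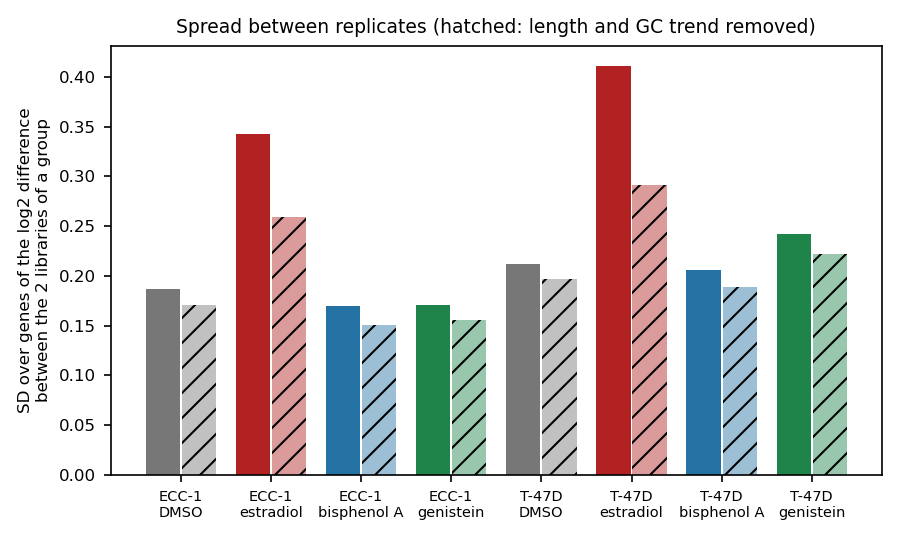
Bars show, for each of the 8 groups, the SD over genes of the log2 difference between the 2 libraries of the group; hatched bars show the same after removal of transcript length and GC trends. The estradiol bars reach 0.343 in ECC-1 and 0.411 in T-47D, above the other groups.

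The largest rise with estradiol in ECC-1 was that of DHRS3. DHRS3, which encodes a retinaldehyde reductase, rose 15-fold, from 1.09 ± 0.475 to 23.5 ± 8.47 scaled RPKM (log2 change 3.91, SE 0.34, adjusted p = 7.1e-06). MMP17, the gene of a membrane-type matrix metalloproteinase, rose from 0.822 ± 0.0732 to 11.8 ± 1.17 (3.21, SE 0.168, adjusted p = 9.33e-08). The chloride channel gene ANO1 rose from 2.95 ± 0.163 to 20.7 ± 0.925 (2.62, SE 0.181), the gel-forming mucin gene MUC5B from 0.785 ± 0.0662 to 7.25 ± 0.49 (2.59, SE 0.155), and the lipase inhibitor gene G0S2 from 2.85 ± 0.145 to 21.4 ± 2.84 (2.70, SE 0.285). DEPDC6, also known as DEPTOR and a partner of the mTOR kinase, rose from 3.47 ± 0.473 to 20.5 ± 0.382 (2.41, SE 0.138, adjusted p = 1.81e-07), and HES2, a basic helix-loop-helix gene, from 9.02 ± 0.245 to 50.4 ± 5.29 (2.41, SE 0.191). TGFA, the gene of a ligand of the epidermal growth factor receptor, rose 3.98-fold from 34.8 ± 0.549 to 140.0 ± 9.25. Thrombospondin gene THBS1 (2.14, SE 0.259), taurine transporter gene SLC6A6 (2.05, SE 0.189) and the cytokine signalling inhibitor gene CISH (2.63-fold) rose too. The placental and germ-cell alkaline phosphatase genes ALPP (2.87, SE 0.215) and ALPPL2 (3.11, SE 0.223) rose together, but their transcripts are near-identical, so which of the pair changed is uncertain.

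Among the falls with estradiol in ECC-1 were those of BMF, TMEM139 and YPEL3. The pro-apoptotic BH3-only gene BMF fell from 1.67 ± 0.0406 to 0.498 ± 0.233 (log2 change -1.14, SE 0.176, adjusted p = 0.00179), TMEM139, which encodes a membrane protein, from 21.8 ± 0.405 to 9.99 ± 1.14 (-1.09, SE 0.127, adjusted p = 0.000153), and YPEL3, a growth-suppressing gene, from 5.51 ± 0.204 to 2.56 ± 0.0402 (-0.97, SE 0.137, adjusted p = 0.000786). Of the 262 changed genes, 196 were higher and 66 lower, and 91 of the rises but 6 of the falls were over 2-fold. The count was 110 without the first and 132 without the second DMSO library, 112 without the first estradiol library and 2148 (1098 higher and 1050 lower) without the second. It was 138 among genes with a mean of at least 5 RPKM, 123 with array weights, 143 in a fit on ECC-1 alone and 665 (406 higher and 259 lower) with length and GC trends removed, the latter chosen after seeing the data.

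Of the panel of 10 estrogen-responsive genes, 4 rose with estradiol in ECC-1. PGR rose from 0.071 ± 0.0327 to 0.774 ± 0.00929 with estradiol (log2 change 1.16, SE 0.184, adjusted p = 0.00226) and stayed under 1 scaled RPKM. GREB1, a coregulator gene of the estrogen receptor, rose from 1.71 ± 0.395 to 4.07 ± 0.622 (1.05, SE 0.212, adjusted p = 0.0157). MYC, a growth-promoting transcription factor gene, rose from 20.7 ± 2.38 to 34.2 ± 1.62 (0.71, SE 0.157, adjusted p = 0.0289), and IGFBP4, the gene of an insulin-like growth factor binding protein, from 0.480 ± 0.0247 to 1.16 ± 0.0661 (0.76, SE 0.135). The GREB1 call ended without the second DMSO library (0.87) or the first estradiol library (0.91), the MYC call without the first DMSO library (0.60), the second DMSO library (0.83) or the first estradiol library (0.66), and the IGFBP4 call without the first (0.73) or second (0.78) DMSO library. The cyclin gene CCND1 (0.37, adjusted p = 0.285), ESR1 itself (-0.24, adjusted p = 0.522), the cytochrome gene CYP1A1 (-0.92, adjusted p = 0.325) and PDZK1 (-0.06) did not pass the test. The chemokine gene CXCL12 and the trefoil peptide gene TFF1 were listed at 0 in both the DMSO and the estradiol libraries of ECC-1.

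**Figure D2:**
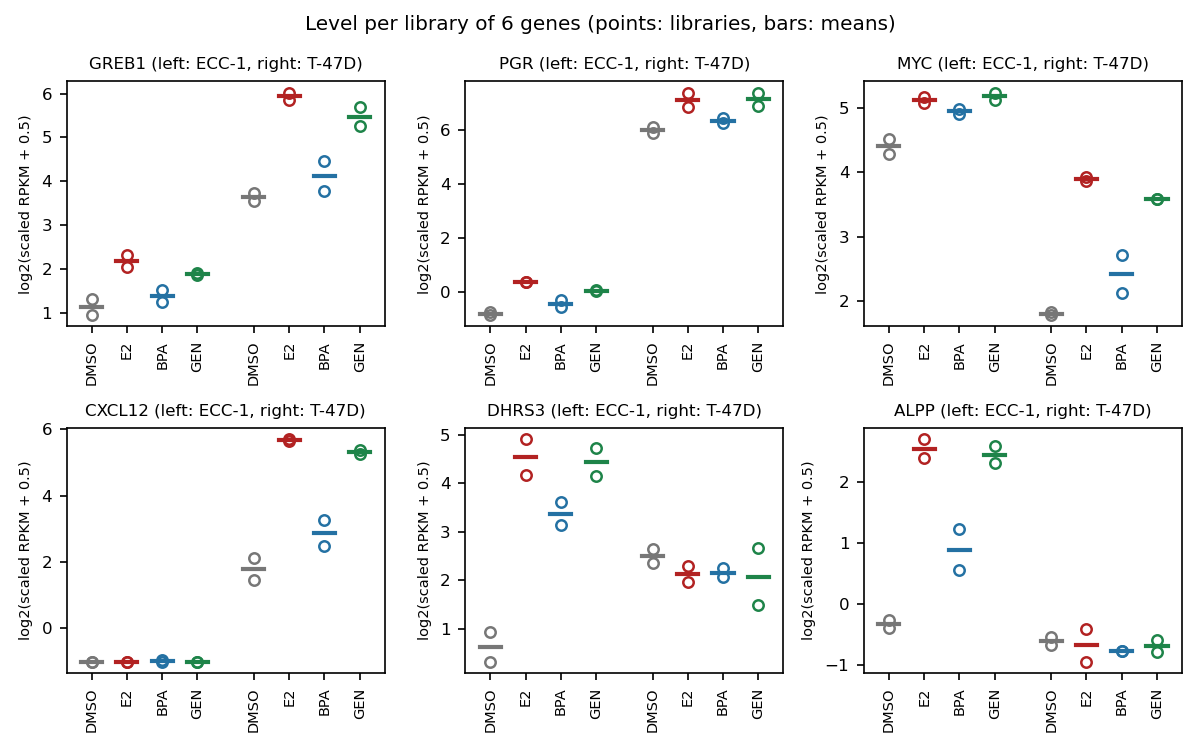
Points show single libraries and bars show group means of log2(scaled RPKM + 0.5) for GREB1, PGR, MYC, CXCL12, DHRS3 and ALPP in each treatment, ECC-1 on the left and T-47D on the right of each panel. DHRS3 and ALPP were raised in ECC-1, and CXCL12 in T-47D, where estradiol took it from 3.06 to 50.4 scaled RPKM.

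BPA raised 27 genes in ECC-1 and lowered 0 in limma, with 347 genes at an unadjusted p under 0.05. DHRS3 rose from 1.09 ± 0.475 to 9.99 ± 2.42 scaled RPKM (log2 change 2.74, SE 0.34, adjusted p = 0.00115), and DEPDC6 rose 4.34-fold from 3.47 ± 0.473 to 16.7 ± 1.25 (2.12, SE 0.138, adjusted p = 2.25e-06). MMP17 rose from 0.822 ± 0.0732 to 3.87 ± 0.372 (1.72, SE 0.168, adjusted p = 0.000102), and HES2 from 9.02 ± 0.245 to 27.2 ± 2.11 (1.54, SE 0.191). The neurotrophic factor gene NRTN rose from 8.62 ± 2.31 to 26.2 ± 2.41 (1.57, SE 0.176, adjusted p = 0.000487), and TGFA from 34.8 ± 0.549 to 96.6 ± 10.4 (1.46, SE 0.122, adjusted p = 3.4e-05). ESPNP, a pseudogene of the actin-bundling protein gene ESPN, rose from 13.6 ± 0.904 to 39.3 ± 1.22, a value that reads from ESPN could carry. ALPPL2 (1.58, adjusted p = 0.00372) passed the test with all libraries, not without the first DMSO library (1.41) or the first BPA library (1.23), and not with a pseudocount of 0.1 (2.12). Of the 27 rises, 20 were over 2-fold. The count was 11 without the first DMSO library and 10 without the first BPA library. It was 68 with array weights, 9 in a fit on ECC-1 alone and 16 with a pseudocount of 0.1. With both first estradiol libraries omitted, chosen after seeing the data, it was 41.

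No gene of the panel passed the test with BPA in ECC-1. MYC stood at 30.3 ± 1.2 against 20.7 ± 2.38 scaled RPKM (log2 change 0.54, 95% interval 0.21 to 0.88, adjusted p = 0.74), PGR at 0.235 ± 0.0943 against 0.071 ± 0.0327 (0.36) and GREB1 at 2.11 ± 0.348 against 1.71 ± 0.395 (0.24, 95% interval -0.21 to 0.69). IGFBP4 (0.26), CCND1 (0.12), PDZK1 (0.07), ESR1 (-0.12) and CYP1A1 (-0.91, SE 0.432) had adjusted p-values of 1. TFF1 and CXCL12 were each listed above 0 in 1 BPA library, at 0.086 and 0.0226 scaled RPKM, under the level of 3 reads in that library (0.238 and 0.0706).

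Genistein raised 112 genes in ECC-1 and lowered 22. DHRS3 rose to 21.6 ± 6.21 scaled RPKM (log2 change 3.80, SE 0.34, adjusted p = 1.09e-05), MMP17 to 9.59 ± 1.76 (2.92, SE 0.168, adjusted p = 3.56e-07), ANO1 to 18.2 ± 0.882 (2.44, SE 0.181, adjusted p = 1.61e-06), MUC5B to 5.53 ± 0.228 (2.23, SE 0.155) and DEPDC6 to 18.5 ± 1.09 (2.26, SE 0.138). TGFA rose 3.64-fold to 127.8 ± 1.5, and the carbonic anhydrase gene CA12 rose 3.48-fold to 9.21 ± 0.665. The near-identical ALPP (2.77, SE 0.215) and ALPPL2 (3.06, SE 0.223) rose, and G0S2 rose by 2.29 (SE 0.285, adjusted p = 0.000336), a call that ended with a pseudocount of 0.1 (2.44). TMEM139 fell from 21.8 ± 0.405 to 10.8 ± 0.686 (1.97-fold lower, adjusted p = 0.000531). BMF was lower (-1.08, adjusted p = 0.0042), a call that ended without the second DMSO library (-1.06) or the first genistein library (-0.99). FGFR2, a fibroblast growth factor receptor gene, was lower (-0.92 with SE 0.137), a call that ended without the first DMSO library (-0.84).

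The panel calls with genistein in ECC-1 were close to the threshold. MYC rose to 35.9 ± 1.89 (log2 change 0.78, adjusted p = 0.0229), PGR to 0.520 ± 0.0179 (0.84, adjusted p = 0.0424) and IGFBP4 to 1.02 ± 0.121 (0.64, adjusted p = 0.033). All 3 calls ended on leaving out any 1 library, and those of PGR (0.51) and IGFBP4 (0.45) also with a pseudocount of 1, and that of PGR with quantile normalization (0.89). Without the first DMSO, second DMSO, first genistein and second genistein library, in that order, MYC stood at 0.67, 0.90, 0.73 and 0.83, PGR at 0.90, 0.78, 0.86 and 0.82, and IGFBP4 at 0.61, 0.66, 0.72 and 0.55. GREB1 (0.76, 95% interval 0.31 to 1.21, adjusted p = 0.169), CCND1 (0.19), ESR1 (-0.29), CYP1A1 (-0.92) and PDZK1 (-0.16) did not pass the test. The count of 134 changed genes, of which 65 rises and 2 falls were over 2-fold, was 70 without the first and 62 without the second DMSO library, 58 without the first and 69 without the second genistein library. It was 83 among genes with a mean of at least 5 RPKM and 841 (479 higher and 362 lower) with array weights. With length and GC trends removed it was 289 (204 higher and 85 lower), and with both first estradiol libraries omitted 410 (288 higher and 122 lower), both chosen after seeing the data.

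Estradiol in T-47D raised 7 genes of the panel of 10. CXCL12 rose 14.7-fold, from 3.06 ± 1.12 to 50.4 ± 1.68 scaled RPKM (log2 change 3.88, SE 0.221, adjusted p = 3.14e-07). TFF1 was measured at 4.40 and 3.97 in the estradiol libraries, against 0.392 and 0 in the DMSO libraries (adjusted p = 6.13e-05). GREB1 rose from 12 ± 1.1 to 60.9 ± 5.15 (2.30, SE 0.212, adjusted p = 1.57e-05), MYC from 3.01 ± 0.0814 to 14.4 ± 0.393 (2.09, SE 0.157, adjusted p = 2.99e-06) and PGR from 63.4 ± 7.15 to 137.8 ± 35.1 (1.09, SE 0.184, adjusted p = 0.00284). The scaffold protein gene PDZK1 rose from 1.87 ± 0.395 to 6.83 ± 0.376 (1.64, SE 0.16) and IGFBP4 from 89.1 ± 1.6 to 223.7 ± 10.8 (1.32, SE 0.135). The glycoprotein hormone gene STC2 rose from 24.3 ± 5.94 to 129.7 ± 5.27, SUSD3 from 3.49 ± 0.539 to 23.3 ± 3.74 and the secreted olfactomedin gene OLFM1 from 7.37 ± 1.46 to 46.1 ± 14. The potassium channel genes KCNK5 (2.43, SE 0.178) and KCNH1 (2.11, SE 0.199), the keratin gene KRT13 (2.32, SE 0.152), NKAIN1 (2.52, SE 0.164) and the cation efflux transporter gene SLC47A1 (2.26, SE 0.187) rose as well. CCND1 (0.40, adjusted p = 0.232), ESR1 (0.24, adjusted p = 0.558) and CYP1A1 (-0.72, adjusted p = 0.469) did not pass the test.

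Among the falls with estradiol in T-47D, those of KCNC1, EFNB2 and IL1R1 were the largest. The potassium channel gene KCNC1 fell from 4.97 ± 0.407 to 1.80 ± 0.674 scaled RPKM (log2 change -1.28, SE 0.168, adjusted p = 0.000332), the ephrin ligand gene EFNB2 from 8.38 ± 0.35 to 3.19 ± 0.291 (-1.27, SE 0.166, adjusted p = 0.000313) and the interleukin 1 receptor gene IL1R1 from 34.2 ± 1.8 to 14.2 ± 1.3 (-1.24, SE 0.174, adjusted p = 0.000572). The sphingosine phosphate receptor gene S1PR3 (-1.14, SE 0.164), ENC1 (-1.06, SE 0.143), the immune checkpoint ligand gene VTCN1 (-1.06, SE 0.171), the protocadherin gene PCDH7 (-1.04, SE 0.147) and the hypoxia-inducible factor gene EPAS1 (-0.94, SE 0.148) also fell. In all, 291 genes were higher and 154 lower, with 123 rises and 10 falls over 2-fold. The count of 445 was 238 without the first and 162 without the second DMSO library, 272 without the first estradiol library and 3113 (1544 higher and 1569 lower) without the second. It was 258 among genes with a mean of at least 5 RPKM, 92 with array weights, 127 in a fit on T-47D alone and 938 (502 higher and 436 lower) with length and GC trends removed, the last chosen after seeing the data.

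No gene passed the test with BPA in T-47D. CXCL12 stood at 5.13 and 9.20 scaled RPKM in the BPA libraries against 3.85 and 2.26 in the DMSO libraries (log2 change 1.09, 95% interval 0.62 to 1.56, adjusted p = 1). MYC stood at 4.99 ± 1.59 against 3.01 ± 0.0814 (0.61, 95% interval 0.28 to 0.95), GREB1 at 17.4 ± 5.96 against 12 ± 1.1 (0.48, 95% interval 0.03 to 0.93), PDZK1 at 2.55 ± 0.325 against 1.87 ± 0.395 (0.37) and PGR at 80.0 ± 7.34 against 63.4 ± 7.15 (95% interval of the change -0.06 to 0.73). IGFBP4 (0.16), CCND1 (0.08), ESR1 (0.12) and CYP1A1 (0.20) had adjusted p-values of 1, and TFF1 was measured at 0.393 and 0. The limma count was 0 higher and 0 lower, with 116 genes at an unadjusted p under 0.05. It was 3 without the first BPA library. In simulated data on these groups, with 200 genes changed per comparison, recovery was 90.4% at a log2 change of 1 and 16.8% at 0.5. Adjustment is stricter where few genes change, so the share at 1 does not tell how well such a change would be found here. Changes of the smaller size lay mostly under what 2 libraries per group could show.

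Genistein raised 108 genes in T-47D and lowered 3. CXCL12 rose 11.4-fold to 39.1 ± 2.37 scaled RPKM (log2 change 3.51, SE 0.221, adjusted p = 1.28e-06). GREB1 rose to 44.5 ± 9.4 (1.84, SE 0.212, adjusted p = 0.000307) and MYC 3.42-fold to 11.5 ± 0.0223 (adjusted p = 7.35e-05). SUSD3 rose to 17.1 ± 0.541 (2.15, SE 0.267), OLFM1 to 29.1 ± 1.37 (1.92, SE 0.21), STC2 to 85.8 ± 11.7 (1.82, SE 0.196), KCNK5 to 2.05 ± 0.756 (1.88, SE 0.178) and KCNH1 to 6.40 ± 1.69 (1.83, SE 0.199). PGR rose to 140.7 ± 33.8 (1.13, adjusted p = 0.00503), IGFBP4 1.78-fold (adjusted p = 0.00456) and PDZK1 by 0.86 (adjusted p = 0.0143), and TFF1 was measured at 2.00 and 0.80 (adjusted p = 0.0382). CCND1 (0.34), ESR1 (0.37, adjusted p = 0.884) and CYP1A1 (-0.02) did not pass the test.

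Several of the genistein calls in T-47D ended when 1 library was left out, some of them with little change in size. The PGR call ended without the first DMSO library (1.01) or the second genistein library (0.88), and the TFF1 call without the second DMSO library (1.02), without the first genistein library (0.96), with quantile normalization (1.34) or with a pseudocount of 0.1 (2.63). The PDZK1 call ended without the second DMSO (0.69), first genistein (0.88) or second genistein (0.84) library, and the IGFBP4 call without the first DMSO (0.82), second DMSO (0.86) or second genistein (0.80) library. The 3 genes that were lower were the serine protease gene TMPRSS2 (-0.84, adjusted p = 0.0128), KCNC1 (-0.79, adjusted p = 0.0396) and the adaptor gene SH2D4A (1.54-fold lower, adjusted p = 0.0363). Without the first DMSO, second DMSO or second genistein library, all 3 calls ended, with TMPRSS2 at -0.81, -0.86 and -0.76, KCNC1 at -0.86, -0.71 and -0.83 and SH2D4A at -0.63, -0.61 and -0.46. The KCNC1 call also ended without the first genistein library (-0.74) or with a pseudocount of 0.1 (-0.87). The total of 111 was 68 without the first and 53 without the second DMSO library and 47 without the second genistein library. It was 55 among genes with a mean of at least 5 RPKM, 206 with array weights and 13 in a fit on T-47D alone. With length and GC trends removed it was 227 (185 higher and 42 lower), and with both first estradiol libraries omitted 271 (216 higher and 55 lower), both chosen after seeing the data.

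Genistein and BPA, both at 100 nM, were compared directly. In T-47D, 53 genes were higher and 3 lower with genistein than with BPA. CXCL12 was higher by a log2 difference of 2.42 (95% interval 1.95 to 2.89, adjusted p = 0.000216), NKAIN1 by 1.69 (1.34 to 2.04, adjusted p = 0.00025), KRT13 by 1.33 (1.00 to 1.65, adjusted p = 0.00139) and MYC by 1.16 (0.83 to 1.5, adjusted p = 0.00328). GREB1 was higher by 1.36 (0.91 to 1.81, adjusted p = 0.00733) and OLFM1 by 1.70 (1.25 to 2.15, adjusted p = 0.00227). The GREB1 call ended without the first BPA library (1.01) or the second genistein library (1.14), and the OLFM1 call without the first BPA library (1.38). PGR (0.79, 95% interval 0.40 to 1.18, adjusted p = 0.114) and TFF1 (1.43, adjusted p = 0.0638) did not pass. The 3 lower genes were the cancer-testis antigen genes GAGE12F (-1.21), GAGE7 (-0.74) and GAGE12I (-0.73), near-identical copies that cannot be told apart with certainty. Their calls ended without the first BPA (-1.11, -0.65 and -0.65) or the first genistein (-0.96, -0.84 and -0.77) library, and those of GAGE7 and GAGE12I also without the second BPA (-0.82 and -0.81) or the second genistein (-0.63 and -0.69) library, or with a pseudocount of 0.1 (-0.95 and -0.94). That of GAGE7 ended without scaling (-0.73) too. The total of 56 fell to 5 without the first BPA library and 10 without the second genistein library. It was 26 among genes with a mean of at least 5 RPKM, 96 with array weights and 0 in a fit on T-47D alone, with 477 genes at an unadjusted p under 0.05 there.

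In ECC-1, 6 genes were higher with genistein than with BPA and 0 lower in limma, with 206 at an unadjusted p under 0.05. The serine kinase gene PIM1 stood at 7.42 ± 0.321 scaled RPKM with genistein and 2.80 ± 0.196 with BPA (log2 difference 1.26, 95% interval 0.96 to 1.57, adjusted p = 0.00346), and MMP17 at 9.59 ± 1.76 and 3.87 ± 0.372 (1.2, adjusted p = 0.00974). ALPP (1.56), ALPPL2 (1.49), the natriuretic peptide gene NPPC (1.43) and the sphingolipid desaturase gene DEGS2 (0.92) made up the rest. All 6 calls ended without the second BPA library, where PIM1 stood at 1.2 and MMP17 at 1.11, or without the first genistein library, at 1.22 and 1.02. Without the second genistein library 3 calls were left, and in a fit on ECC-1 alone 0, with 323 genes at an unadjusted p under 0.05. The calls of ALPP (1.81) and ALPPL2 (1.64) also ended with a pseudocount of 0.1, and that of DEGS2 with length and GC trends removed (0.83), an alternative chosen after seeing the data. DHRS3 (1.06, 95% interval 0.34 to 1.79), DEPDC6 (0.15, -0.15 to 0.44), TGFA (0.41, 0.15 to 0.67), GREB1 (0.52, 0.06 to 0.97) and CA12 (0.80, adjusted p = 0.188) did not pass the test.

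Against estradiol, given at a 10th of the molar dose, BPA responses were smaller. In ECC-1, 2 genes were higher and 19 lower with BPA than with estradiol, among them PIM1 (2.80 ± 0.196 against 8.61 ± 0.686, log2 difference -1.46, SE 0.143, adjusted p = 0.00052) and MMP17 (-1.49, adjusted p = 0.00176). The MMP17 call ended without the first estradiol library (-1.38) or the second BPA library (-1.4). The higher genes were TRIM43 (1.05, adjusted p = 0.0326) and the small nucleolar RNA gene SNORA25, listed at 0 in both estradiol libraries and named after its values were seen. TRIM43 is near-identical to TRIM43B, and its call ended without the first estradiol (0.90), first BPA (1.07) or second BPA (1.04) library, or with a pseudocount of 0.1 (1.28). The total of 21 was 2 without the first estradiol library, 953 without the second, 13 without the first BPA library and 1 without the second. It was 2 with array weights and 1 in a fit on ECC-1 alone. In T-47D, 135 genes were higher and 199 lower with BPA. CXCL12 (-2.78, SE 0.221, adjusted p = 1.08e-05), NKAIN1 (-2.48, SE 0.164), KRT13 (-2.16, SE 0.152), GREB1 (-1.82, adjusted p = 0.000212) and MYC (-1.47, adjusted p = 0.000101) were lower, and TFF1 was measured at 0.393 and 0 against 4.40 and 3.97. KCNC1 (1.24, SE 0.168), IL1R1 (1.24, SE 0.174) and EFNB2 (1.15, SE 0.166) were higher. The total of 334 was 211 without the first estradiol library, 2896 without the second, 126 without the first BPA library and 171 without the second. It was 55 with array weights and 63 in a fit on T-47D alone.

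Few genes passed the test between genistein and estradiol. In ECC-1 limma called 0 genes, with 387 at an unadjusted p under 0.05, and the differences of DHRS3 (-0.10, 95% interval -0.83 to 0.62), TGFA (-0.13, -0.39 to 0.13) and CA12 (-0.20, -0.54 to 0.15) included 0. In T-47D the transcriptional coactivator gene CITED1 was the 1 gene called, at 0.389 ± 0.0562 scaled RPKM with genistein against 1.92 ± 0.306 with estradiol (log2 difference -1.44, SE 0.165, adjusted p = 0.00435), with 1004 genes at an unadjusted p under 0.05. Its call ended without the second genistein library (-1.38) or with a pseudocount of 0.1 (-2.04), and no gene was called without the first estradiol library, with array weights or in a fit on T-47D alone (277 and 679 at an unadjusted p under 0.05 in the last 2). Without the second estradiol library 1875 genes were called. The T-47D differences of CXCL12 (-0.36, 95% interval -0.84 to 0.11), MYC (-0.31, -0.65 to 0.02) and PGR (0.03, -0.36 to 0.43) included 0, while those of PDZK1 (-0.78, -1.12 to -0.44), TFF1 (-1.38, -2.02 to -0.73), IGFBP4 (-0.49, -0.77 to -0.20), GREB1 (-0.46, -0.91 to -0.01), DEPDC6 (-0.59, -0.88 to -0.29) and TGFA (-0.33, -0.59 to -0.07) did not, without passing adjustment.

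The size of each compound's response was also measured over all genes changed by estradiol in the line, as the median change in the direction of estradiol over the median estradiol change. For genistein it was 0.808 in ECC-1 (0.792 and 0.825 in the single libraries), with 262 of 262 genes moving as with estradiol, and 0.624 in T-47D (0.620 and 0.664), with 444 of 445. For BPA it was 0.420 in ECC-1 (0.479 and 0.376), with 259 of 262 genes, and 0.121 in T-47D (0.0445 and 0.183), with 364 of 445 genes or 81.8%. Because the compound and estradiol share the DMSO libraries, simulated data without a compound response gave 0.0244 for BPA in ECC-1 (highest of 50 draws 0.0438) and 0.0574 in T-47D (highest 0.0795), with 62.3% of genes in the same direction (highest 66.3%). The first T-47D BPA library alone, at 0.0445, lay under the simulated value of 0.0574 without a response. Genes were chosen by the estradiol test, which can lower the relative size. Without the second estradiol library it was 0.275 for genistein and 0.152 for BPA in ECC-1, and 0.169 and 0.0531 in T-47D. Without the first, ECC-1 genistein gave 0.911. The T-47D BPA value was 0.0400 without the second BPA library, 0.183 without the first and 0.196 without the first DMSO library. With separate DMSO libraries for estradiol and BPA it was 0.180 or 0.0615.

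**Figure D3:**
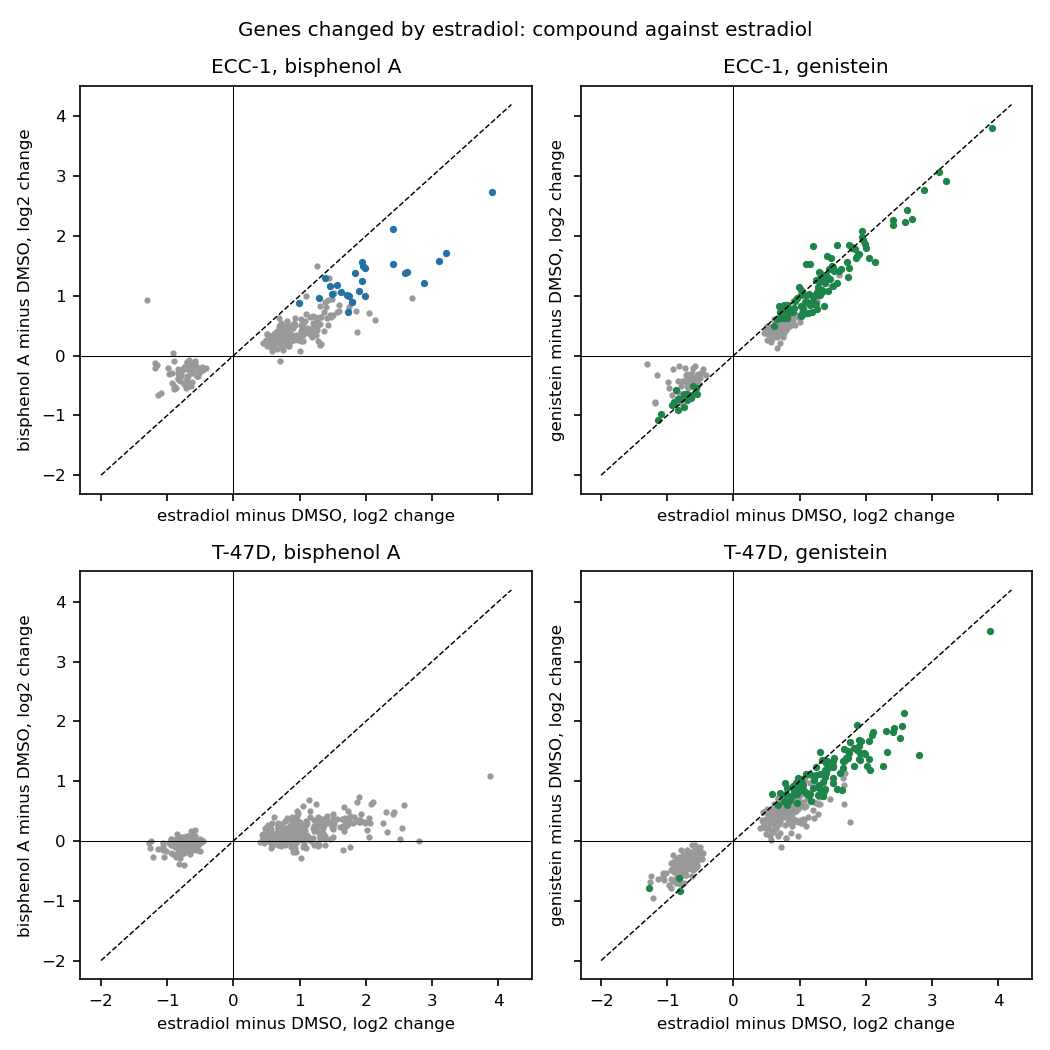
Each point is a gene changed by estradiol in the line, with its log2 change with estradiol on the x axis and with BPA or genistein on the y axis; coloured points also passed the test for the compound, grey points did not, and the dashed line marks equal change. Genistein points lie on the whole nearer to the line than BPA points, and further from it in T-47D (relative size 0.624) than in ECC-1 (0.808). Of the BPA points 27 are coloured in ECC-1 and 0 in T-47D.

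In the main fit, most genes called with BPA or genistein were also called with estradiol, and fewer the other way round. With array weights, which give the estradiol libraries less weight, more genes were called with genistein than with estradiol in both lines. Most genistein calls could then not be shared with estradiol. All 27 genes raised by BPA in ECC-1, DHRS3, DEPDC6 and TGFA among them, were also raised by estradiol and by genistein, where independent lists would share 0.383 and 0.219. Of the 112 genes raised by genistein in ECC-1, 107 were raised by estradiol (1.59 for independent lists), and of the 22 lowered, TMEM139 and BMF among them, 19 were lowered (0.105). In T-47D, 107 of 108 genes raised by genistein and 3 of 3 lowered were also changed by estradiol (2.27 and 0.0334 for independent lists). Of the genes raised by estradiol, BPA raised 27 of 196 and genistein 107 of 196 in ECC-1, and genistein raised 107 of 291 in T-47D. Of those lowered by estradiol, genistein lowered 19 of 66 in ECC-1 and 3 of 154 in T-47D. The covariance across genes of the estradiol and BPA changes in ECC-1 was 0.0302 against 0.00871 simulated, and that of estradiol and genistein 0.0512 against 0.00871. In T-47D these were 0.0109 for BPA and 0.0423 for genistein, each against 0.0113 simulated. Correlated replicate differences were not simulated, so the value for BPA does not exclude a response. The numbers for independent lists ignore the shared DMSO libraries, which were not split here, so part of the excess overlap may come from them. Simulated data with these but no compound effect, in which few genes can be called at all, gave 0 shared calls in 50 draws.

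Few genes were called with estradiol in both lines. Changes near log2 0.5 mostly go uncalled, so a call in 1 line does not exclude a response in both. In total 27 genes rose in both (4.12 for independent lists), including CA12 (log2 change 1.99 in ECC-1 and 1.21 in T-47D), TGFA (1.99 and 0.96), THBS1 (2.14 and 1.81), CISH (1.4 and 1.29), DEPDC6 (2.41 and 0.67), PGR (1.16 and 1.09), GREB1 (1.05 and 2.30), MYC (0.71 and 2.09) and IGFBP4 (0.76 and 1.32). The 3 genes that fell in both were BLNK (-0.53 and -0.50), GPR110 (-0.74 and -0.69) and IGFBP3 (-0.64 and -0.78). Genistein raised 12 genes in both lines (0.875 for independent lists). Another 3 genes, named after their values were seen, moved in opposite directions with estradiol: the interleukin 4 receptor gene IL4R (1.03 in ECC-1 and -0.61 in T-47D), the axon guidance receptor gene ROBO2 (0.76 and -0.65) and VASN (0.80 and -0.63). Their differences between the lines (-1.63, -1.41 and -1.43) kept passing without any 1 library, while all of their single-line calls except that of IL4R in ECC-1 ended in at least 2 of 4 such fits, in which IL4R in T-47D ranged from -0.82 to -0.40.

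Differences between the lines were tested as interactions, T-47D minus ECC-1. The estradiol response differed for 239 genes, with 123 differences above 0 and 116 below 0, signs that do not tell which line had the larger change. DHRS3 (log2 difference -4.28, SE 0.48, adjusted p = 0.000212), MMP17 (-3.09, SE 0.237, adjusted p = 2e-05), MUC5B (-2.54, SE 0.22), the prostaglandin transporter gene SLCO2A1 (-2.44, SE 0.267) and ANO1 (-2.33, SE 0.255) responded more in ECC-1. SUSD3 (2.66, SE 0.378, adjusted p = 0.00124), NKAIN1 (2.36, SE 0.232), the troponin gene TNNI2 (2.44, SE 0.372), AGR3 (2.25, SE 0.257), KCNK5 (2.24, SE 0.251), PDZK1 (1.70, adjusted p = 0.000716) and MYC (1.37, adjusted p = 0.00323) responded more in T-47D. CXCL12 and OLFM1 rose in T-47D and were listed at 0 in both ECC-1 DMSO libraries. KCNK5 stood at 5.68 ± 0.663 in ECC-1 DMSO against 0.176 ± 0.056 in T-47D. The count of 239 was 115 without the first and 146 without the second ECC-1 DMSO library, 112 without the second T-47D DMSO library, 151 without the first and 1715 without the second ECC-1 estradiol library, and 2202 without the second T-47D estradiol library. It was 60 with array weights and 422 with length and GC trends removed.

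For BPA the response differed for 6 genes, all with differences below 0, and for genistein for 81. DEPDC6 differed by -2.16 with BPA (SE 0.196, adjusted p = 0.000208), a call that passed without any 1 library. TGFA differed by -1.45 (SE 0.172, adjusted p = 0.00335), a call that ended without the first ECC-1 BPA library (-1.35). The calls of DHRS3 (-3.08, adjusted p = 0.028), MMP17 (-1.69, adjusted p = 0.0103), ESPN (-1.44, adjusted p = 0.00737) and ESPNP (-1.5, adjusted p = 0.00774) ended without the first ECC-1 DMSO (-2.77, -1.74, -1.44 and -1.43), the second T-47D DMSO (-3.22, -1.68, -1.35 and -1.36), the first ECC-1 BPA (-3.32, -1.60, -1.48 and -1.53) or the first T-47D BPA library (-3.17, -1.63, -1.35 and -1.34). The DHRS3 and MMP17 calls also ended without the first T-47D DMSO (-2.93 and -1.68) or the second T-47D BPA library (-2.98 and -1.74), that of DHRS3 without the second ECC-1 BPA library (-2.84), and that of MMP17 without the second ECC-1 DMSO library (-1.63). The count of 6 was 2 without the first ECC-1 DMSO library, 2 without the second T-47D DMSO library and 1 without the first ECC-1 BPA library. With genistein, DHRS3 (-4.23, SE 0.48), MMP17 (-2.62, SE 0.237), DEPDC6 (-2.18, SE 0.196), ANO1 (-2.24, SE 0.255) and NRTN (-2.14, SE 0.249) responded more in ECC-1, and CXCL12 (3.51), OLFM1 (1.88), KCNH1 (1.84, SE 0.281) and KCNK5 (1.72, SE 0.251) more in T-47D. The count of 81 was 50 without the first ECC-1 DMSO library, 48 without the second T-47D DMSO library, 50 without the first and 50 without the second ECC-1 genistein library, and 45 without the second T-47D genistein library.

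Gene lists fixed from general knowledge were tested with camera at a preset correlation of 0.01 and with an estimated correlation. Estrogen-induced genes of breast cancer cells (41 measured) formed the strongest list in T-47D. With estradiol 31 rose (36 adjusted over the list alone) and all 41 had changes above 0, with a median log2 change of 1.22 (adjusted p = 4.46e-59, and adjusted p = 0.00947 with an estimated correlation). With genistein 23 rose (36 adjusted over the list alone), median 0.86 (adjusted p = 4.98e-80, and adjusted p = 0.00632 with an estimated correlation). With BPA 0 rose in limma (2 adjusted over the list alone), yet 38 of 41 had changes above 0, median 0.19 (adjusted p = 8.8e-20, and adjusted p = 0.038 with an estimated correlation). In fry, which tests the list without reference to other genes, that BPA value was an adjusted p of 0.173. In ECC-1 11 rose with estradiol (12 adjusted over the list alone), CA12 and PGR among them, median 0.22 (adjusted p = 2.05e-08, but adjusted p = 0.219 with an estimated correlation). With BPA 1, CA12, rose (1 adjusted over the list alone), median 0.07 (adjusted p = 1.75e-06, but adjusted p = 0.316 with an estimated correlation). That CA12 call ended without the first DMSO (0.98), second DMSO (1.01) or first BPA (0.87) library. With genistein 6 rose (12 adjusted over the list alone), median 0.16 (adjusted p = 9.55e-10, but adjusted p = 0.18 with an estimated correlation).

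Estrogen-repressed genes of breast cancer cells (12 measured) were lower in both lines. With estradiol 5 fell in ECC-1 (7 adjusted over the list alone), BMF and YPEL3 among them, and 6 in T-47D (9 adjusted over the list alone), IL1R1 among them, with medians of -0.53 in each and adjusted p = 0.0155 with an estimated correlation in each. The calls of ERBB2 (-0.78), TP53INP1 (-0.78) and TGFB3 (-0.57) in T-47D ended without the second DMSO library (-0.63, -0.57 and -0.53), that of TP53INP1 also without the first estradiol library (-0.48) and that of TGFB3 without the first DMSO library (-0.62). The HES1 call in ECC-1 (-0.56) ended without the first DMSO (-0.63), second DMSO (-0.49) or first estradiol (-0.60) library. With genistein 2 fell in ECC-1, BMF and HES1 (5 adjusted over the list alone), median -0.31, and 0 in T-47D in limma (4 adjusted over the list alone), with 11 of 12 below 0, both again with adjusted p = 0.0155 with an estimated correlation. The HES1 call with genistein (-0.54) ended without the first DMSO (-0.61), second DMSO (-0.47), first genistein (-0.55) or second genistein (-0.53) library, without scaling (-0.53) or with quantile normalization (-0.52). Neither it nor the BMF call was left without the second DMSO or the first genistein library. With BPA 0 fell in either line (1 and 0 adjusted over the list alone). The BPA median was -0.22 in ECC-1 (adjusted p = 0.0237 with an estimated correlation) and -0.04 in T-47D (adjusted p = 0.00873, but adjusted p = 0.198 with an estimated correlation).

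Estrogen-linked genes of the endometrium (10 measured) rose in ECC-1. With estradiol 6 rose (6 adjusted over the list alone), among them TGFA, CISH and the near-identical ALPP and ALPPL2, counted as 2 genes though they cannot be told apart with certainty, median 1.11 (adjusted p = 8.1e-10, and adjusted p = 0.0155 with an estimated correlation). With BPA 3 rose, ALPP, ALPPL2 and TGFA (4 adjusted over the list alone), median 0.30 (adjusted p = 0.0119 with an estimated correlation). The ALPP call with BPA (1.21) ended without the first DMSO (1.15), second DMSO (1.28) or first BPA (0.88) library or with a pseudocount of 0.1 (1.86). With genistein 5 rose (6 adjusted over the list alone), median 0.80 (adjusted p = 0.0102 with an estimated correlation). In T-47D 4 rose with estradiol, GREB1, CISH, PGR and TGFA (4 adjusted over the list alone), median 0.59 (adjusted p = 0.000365, but adjusted p = 0.11 with an estimated correlation). The same number rose with genistein (4 adjusted over the list alone), median 0.28 (adjusted p = 0.0285 with an estimated correlation). Of these the calls of CISH (0.93) and TGFA (0.63) ended without any 1 of the 4 libraries, between 0.91 and 0.95 for CISH and 0.58 and 0.68 for TGFA. With BPA 0 rose in T-47D, median 0.07, where camera did not pass.

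**Figure D4:**
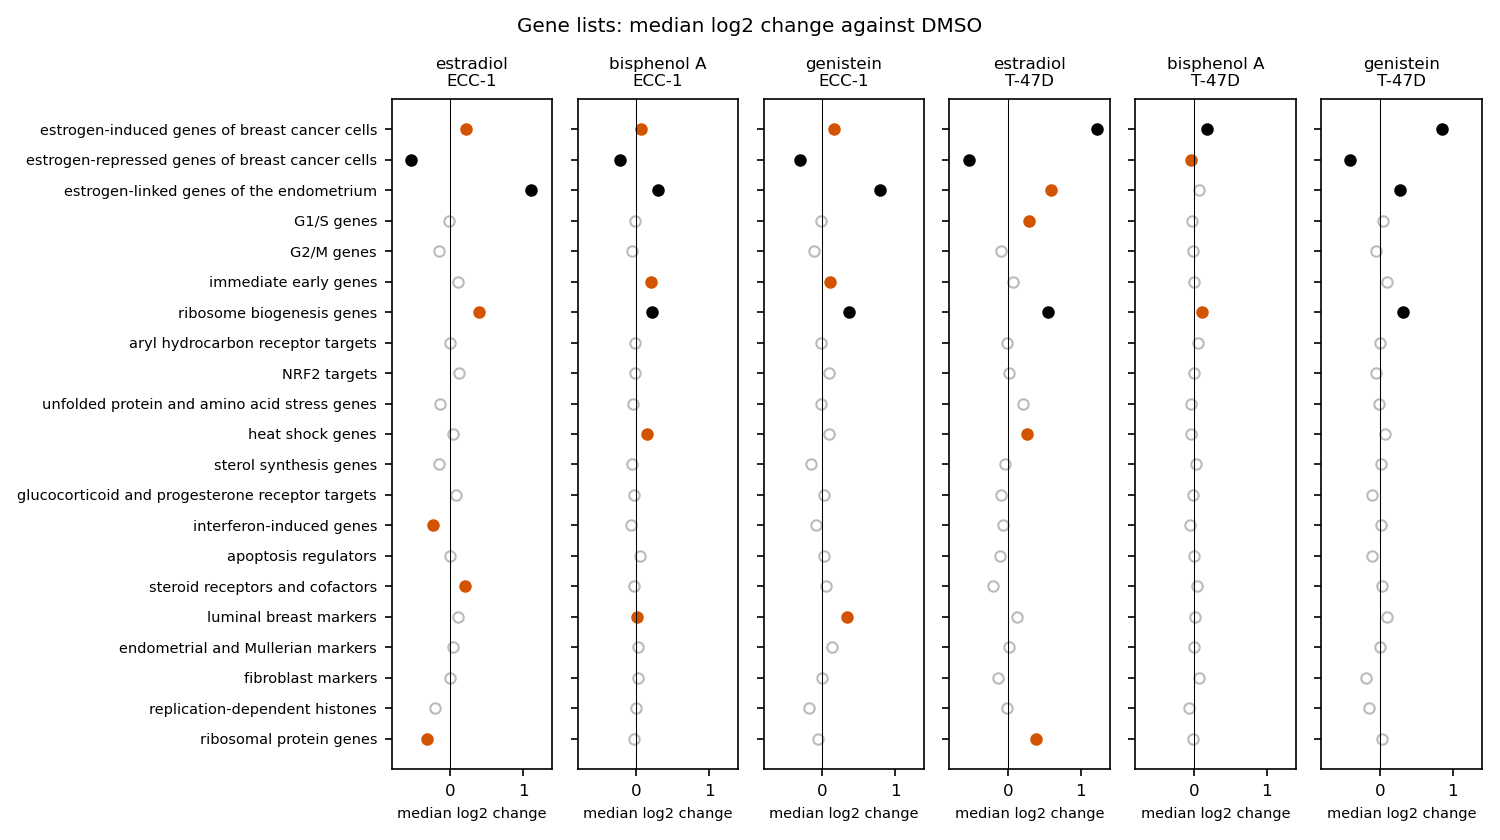
Median log2 change of the members of the tested lists named in the text in the 6 treatment comparisons; black points passed an adjusted p of 0.05 with the preset and the estimated correlation, orange points with the preset alone, and open grey points with neither. Estrogen-induced genes reach a median of 1.22 with estradiol in T-47D.

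Ribosome biogenesis genes, MYC among them, leaned upward in every treatment. With estradiol in T-47D 7 of 16 rose (15 adjusted over the list alone), median 0.54 (adjusted p = 0.0146 with an estimated correlation). With genistein in T-47D MYC alone rose (9 adjusted over the list alone), median 0.32 (adjusted p = 0.0146 with an estimated correlation). In ECC-1 genistein raised MYC alone (10 adjusted over the list alone), median 0.37 (adjusted p = 0.0155 with an estimated correlation). Estradiol there raised MYC alone (10 adjusted over the list alone), median 0.40 (adjusted p = 7.07e-07, but adjusted p = 0.0574 with an estimated correlation). Both ECC-1 MYC calls ended in several fits without 1 library. With BPA no member rose in limma. All 16 had changes above 0 in ECC-1 (0 adjusted over the list alone), median 0.22 (adjusted p = 0.0237 with an estimated correlation), and 13 of 16 in T-47D (1 adjusted over the list alone), median 0.11 (adjusted p = 8.63e-05, but adjusted p = 0.137 with an estimated correlation). No scaling alternative turned these directions. The nucleolar protein genes RRS1 (0.95), BOP1 (0.86) and NOP16 (0.78) rose with estradiol in T-47D. Their calls ended without the first estradiol (0.46, 0.46 and 0.50) or the second DMSO (0.85, 0.85 and 0.63) library, and for RRS1 and BOP1 without the first DMSO library (1.05 and 0.87).

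Cell cycle genes of the G1/S step, such as those of the MCM helicase, leaned upward with estradiol in T-47D. None of the 22 passed limma alone (0 adjusted over the list alone), 18 were above 0, and the median was 0.295 (adjusted p = 0.000239, but adjusted p = 0.54 with an estimated correlation). No other treatment moved the G1/S list past camera, and the G2/M list (17 genes) passed in none, with medians from -0.15 to -0.01. Among immediate early genes (12 measured), which answer growth factors within the hour, the zinc finger gene EGR1 rose in ECC-1 with estradiol from 4.90 ± 1.54 to 14.1 ± 2.51 (log2 change 1.45, SE 0.29, adjusted p = 0.0154) and with genistein to 14.0 ± 1.39 (1.45, adjusted p = 0.0215). Its estradiol call ended without the second DMSO (1.15) or first estradiol (1.27) library, and its genistein call without the second DMSO (1.16), first genistein (1.36) or second genistein (1.55) library, and both ended with a pseudocount of 0.1 (1.53 for each). The list passed camera in ECC-1 with BPA (0 rose, 1 adjusted over the list alone, median 0.21, adjusted p = 7.26e-05, but adjusted p = 0.231 with an estimated correlation). It also passed with genistein (1 rose, 3 adjusted over the list alone, median 0.10, adjusted p = 0.00882, but adjusted p = 0.494 with an estimated correlation), a call that ended with trends removed (0.07) or both first estradiol libraries omitted (0.11), both chosen after seeing the data. With estradiol 2 members rose in each line and the list did not pass.

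Ribosomal protein genes (24 measured), the most abundant list, had medians on opposite sides of 0 with estradiol in the 2 lines, with no member called in either. In ECC-1 all 24 were below 0, median -0.32, with 0 called (0 adjusted over the list alone). Camera gave an adjusted p of 1.67e-05 there, but adjusted p = 0.653 with an estimated correlation. The median was -0.60 in the first estradiol library and -0.02 in the second, and the call ended with quantile normalization (-0.08) or with both first estradiol libraries omitted (-0.02). In T-47D all 24 were above 0, median 0.39, with 0 called (0 adjusted over the list alone, adjusted p = 2.88e-08, but adjusted p = 0.55 with an estimated correlation). Its library values were 0.53 and 0.25.

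The estradiol-changed genes of each line were finally followed as sets in the other line. Genes that rose with estradiol in T-47D (291), CXCL12 and GREB1 among them, had a median change in ECC-1 of 0.14 with estradiol, 0.07 with BPA and 0.14 with genistein. Genes that rose with estradiol in ECC-1 (196), DHRS3 and TGFA among them, had medians in T-47D of 0.12, 0.05 and 0.11. Genes that fell with estradiol in T-47D (154), IL1R1 among them, had medians in ECC-1 of 0.004, -0.08 and -0.07, and those that fell in ECC-1 (66), BMF among them, -0.02, -0.03 and -0.07 in T-47D. The 2 medians of fallen sets with estradiol did not pass camera (adjusted p = 0.391 and 0.0787). Of 12 such tests 10 passed camera with the preset correlation and 0 with an estimated correlation, where the smallest adjusted p was 0.153. The count of 10 was 6 without the second ECC-1 DMSO library.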

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

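Tests of explanations were chosen after the result was seen, except those on read depth, larger T-47D spread and transcripts low in the other line. Those were written down before their values were known.

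The response to estradiol differed between the lines for 239 genes, that to BPA for 6 and that to genistein for 81, each by an interaction test (T-47D minus ECC-1). With estradiol the largest differences toward T-47D were CXCL12 (3.88), TFF1 (2.81), SUSD3 (2.66), OLFM1 (2.55), TNNI2 (2.44), NKAIN1 (2.36), AGR3 (2.25) and KCNK5 (2.24), and the panel genes PDZK1 (1.70), MYC (1.37) and GREB1 (1.25, adjusted p = 0.0495) also differed. CXCL12, TFF1 and OLFM1 were listed at 0 in both ECC-1 DMSO libraries. Toward ECC-1 they were DHRS3 (-4.28), ALPPL2 (-3.25), MMP17 (-3.09), ALPP (-2.94), MUC5B (-2.54), G0S2 (-2.49), SLCO2A1 (-2.44) and ANO1 (-2.33), of which the G0S2 call ended with a pseudocount of 0.1 (-2.14). The differences in the BPA response were those of DHRS3 (-3.08), DEPDC6 (-2.16), MMP17 (-1.69), ESPNP (-1.5), TGFA (-1.45) and ESPN (-1.44), of which DEPDC6 passed without any 1 library. In the genistein response they were CXCL12 (3.51), OLFM1 (1.88), NPY1R (1.87), KCNH1 (1.84), SUSD3 (1.83), FGD3 (1.75), FMN1 (1.74) and KCNK5 (1.72) toward T-47D, and DHRS3 (-4.23), ALPPL2 (-3.13), ALPP (-2.85), MMP17 (-2.62), G0S2 (-2.29), ANO1 (-2.24), DEPDC6 (-2.18) and NRTN (-2.14) toward ECC-1.

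The calls of SUSD3 and G0S2 in the genistein response were among the least stable. That of SUSD3 ended without any 1 of the 8 libraries, between 1.67 without the first ECC-1 genistein library and 1.99 without the second, and also with a pseudocount of 0.1 (1.67) or quantile normalization (1.82). That of G0S2 ended with a pseudocount of 0.1 (-2.44) and without the first ECC-1 DMSO (-2.24), second ECC-1 DMSO (-2.33), first T-47D DMSO (-2.29), second T-47D DMSO (-2.29), second ECC-1 genistein (-2.09) or second T-47D genistein (-2.29) library. The call of FGD3 ended without the second ECC-1 DMSO (1.68), second T-47D DMSO (1.63), first ECC-1 genistein (1.63) or second T-47D genistein (1.64) library, that of NPY1R without the second T-47D DMSO library (1.68) and that of FMN1 without the second T-47D genistein library (1.64).

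The first estradiol library of each line stood apart from the second. Read depth alone would leave abundant genes unaffected, yet among 1659 genes of at least 50 scaled RPKM the SD of the difference between the estradiol libraries was 0.365 in ECC-1 and 0.408 in T-47D, against 0.117 to 0.207 in the other groups. RNA of the other line would bring its abundant transcripts, and the median rise of these was 0.012% of their level in that line in ECC-1 and 0.015% in T-47D (upper decile 0.3% and 0.21%). Trends with transcript length and GC content took part of the spread, with an r2 of 0.432 in ECC-1 and 0.496 in T-47D, but with the trends removed SDs of 0.259 and 0.291 remained, against 0.151 to 0.222 in the other groups, so these trends were not the whole of it. What else set these libraries apart stays open, and no biological explanation was tested.

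BPA changed 27 genes in ECC-1 and none passed the test in T-47D. A larger spread in T-47D hiding a response of the same size would leave the relative size alike, but over the 30 genes changed by estradiol in the same direction in both lines the higher T-47D library gave 0.2, against 0.318 to 0.483 in ECC-1. With separate DMSO libraries for estradiol and BPA the higher T-47D value was 0.18, against 0.388 to 0.477 in ECC-1. The genes had been chosen with both DMSO libraries, so chance values of the shared controls are not excluded. Less estrogen receptor transcript in T-47D does not match the values either, since ESR1 was not lower there (log2 difference 0.53, 95% interval 0.15 to 0.90). A weaker response to BPA in T-47D may thus be a difference between the lines, a hypothesis found and tested on the same libraries, and protein levels, uptake and metabolism of BPA were not measured.

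The median change of ribosomal protein genes with estradiol was below 0 in ECC-1 and above 0 in T-47D, with no member called and neither list passing with an estimated correlation. In ECC-1 the second estradiol library alone gave a median of -0.02, so the lower median is consistent with an effect of the first library. In T-47D the second library alone gave 0.25, so the first library was not the whole source there. A biological difference between the lines stays open and was not tested.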

How the results depend on the processing

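Single calls were followed for named genes and lists only. Named genes were followed over scaling, pseudocounts, the block, trend removal and left-out libraries, and lists over scaling, a pseudocount of 0.1, the block, trend removal, omission of both first estradiol libraries and the estimated correlation. None of these calls turned direction there. Of 245 calls of named genes 144 held throughout and 101 ended in at least 1 alternative, and of 36 list calls 16 held and 20 ended. Filters, array weights, robust eBayes, sums over transcripts and the fit on the same line were run only for counts of genes or relative sizes. With an estimated correlation 16 list calls and 0 of the 10 calls of sets from the other line were left, and fry left 18 list calls. The BPA count in T-47D stayed 0 in every alternative that kept all groups at 2 libraries. Leaving 1 library out assumes that the lone library varies like the other groups. Omitting the second, better correlated estradiol library raised several counts, and the cause was not tested.

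Counts are given in the order ECC-1 estradiol, ECC-1 genistein, T-47D estradiol, T-47D genistein, estradiol interaction and genistein interaction. With a mean of at least 5 RPKM they were 138, 83, 258, 55, 113 and 48. With array weights they were 123, 841, 92, 206, 60 and 205, where the estradiol libraries had weights of 0.249 in T-47D and 0.352 in ECC-1. With length and GC trends removed they were 665, 289, 938, 227, 422 and 133. In a fit on the same line ECC-1 estradiol gave 143, T-47D estradiol 127 and T-47D genistein 13. With both first estradiol libraries omitted ECC-1 genistein gave 410, T-47D genistein 271 and the genistein interaction 145. BPA in ECC-1 gave 16 with a pseudocount of 0.1, 68 with array weights, 9 in a fit on the same line and 41 with both first estradiol libraries omitted. The BPA interaction gave 11 with a pseudocount of 1, 23 with array weights, 10 with trends removed and 18 with both first estradiol libraries omitted.

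Between treatments, genistein against BPA in ECC-1 gave 11 with a pseudocount of 1, 11 without a filter, 2 with a mean of at least 5 RPKM, 52 with array weights, 0 in a fit on the same line and 15 with both first estradiol libraries omitted. In T-47D it gave 26 with a mean of at least 5 RPKM, 96 with array weights, 0 in a fit on the same line, 91 with trends removed and 102 with both first estradiol libraries omitted. BPA against estradiol gave, in ECC-1 and T-47D, 12 and 184 with a mean of at least 5 RPKM, 2 and 55 with array weights, 1 and 63 in a fit on the same line, 43 and 739 with trends removed, and 12 and 537 with both first estradiol libraries omitted. Genistein against estradiol gave 2 in ECC-1 without a filter. In T-47D it gave 7 without a filter, 0 with a pseudocount of 0.1, a mean of at least 5 RPKM, array weights or a fit on the same line, 4 with trends removed and 3 with both first estradiol libraries omitted.

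Libraries with the same replicate number were not paired. Correlations of replicate differences between groups were not all over 0.1 (-0.19 to 0.301 in ECC-1, -0.224 to 0.408 in T-47D). With trends removed they were -0.039 to 0.316 and 0.01 to 0.371. T-47D pairs without estradiol lay at 0.208 to 0.408, so a shared day or batch is not excluded. With the number as a block, genistein against BPA in ECC-1 gave 10, BPA against estradiol in ECC-1 43 and genistein against estradiol in T-47D 3. The block ended 4 of the 245 calls of named genes, among them KCNC1 with genistein in T-47D (adjusted p = 0.051) and GAGE7 (0.0621) and GAGE12I (0.053) between genistein and BPA. With the block and trends removed, ECC-1 gave 979 for estradiol, 46 for BPA and 392 for genistein, T-47D 1221 (628 higher and 593 lower) for estradiol and 301 (216 and 85) for genistein, and the interactions 625 for estradiol, 13 for BPA and 192 for genistein. Genistein against BPA gave 13 and 133, BPA against estradiol 55 and 1096 (ECC-1 and T-47D) and genistein against estradiol in T-47D 5. The relative size of the ECC-1 genistein response was 0.753 in that block fit.

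That size was 0.771 with a pseudocount of 0.1, 0.776 without a filter, 0.767 with trends removed and 0.764 or 0.835 with separate DMSO libraries. For T-47D genistein it was 0.583 with quantile normalization, 0.726 or 0.539 with separate DMSO libraries and 0.538 with both first estradiol libraries omitted.

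With 1 library left out, counts ranged from 110 to 2148 for estradiol, 10 to 20 for BPA and 58 to 70 for genistein in ECC-1, and from 162 to 3113, 0 to 3 and 47 to 99 in T-47D. Interactions ranged from 112 to 2202, 1 to 8 and 45 to 80. Genistein against BPA ranged from 0 to 9 in ECC-1 and 5 to 63 in T-47D, BPA against estradiol from 1 to 953 and 126 to 2896, genistein against estradiol from 0 to 0 and 0 to 1875, T-47D against ECC-1 from 9548 to 9869, and the calls of sets from the other line from 6 to 11. Relative sizes ranged from 0.152 to 0.504 for BPA and 0.275 to 0.911 for genistein in ECC-1, and from 0.0400 to 0.196 and 0.169 to 0.697 in T-47D.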

Other observations

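Heat shock genes, which encode protein chaperones, had small changes. With BPA in ECC-1 all 9 were above 0, with 0 called (0 adjusted over the list alone), median 0.16 (adjusted p = 0.00347, but adjusted p = 0.316 with an estimated correlation). With estradiol in T-47D 1 rose, the mitochondrial chaperonin gene HSPD1 (log2 change 0.49, adjusted p = 0.0401, 1 adjusted over the list alone), median 0.27 (adjusted p = 0.0444, but adjusted p = 0.54 with an estimated correlation). The HSPD1 call ended without the first (0.49) or second (0.48) DMSO library, and the list call with quantile normalization (0.13). Of 11 interferon-induced genes 0 were called with estradiol in ECC-1 (0 adjusted over the list alone), with 10 below 0 and a median of -0.23 (adjusted p = 0.0178, but adjusted p = 0.263 with an estimated correlation). That call ended with trends removed (-0.31) or with both first estradiol libraries omitted (-0.15), both chosen after seeing the data. Luminal breast markers (9 measured) passed camera in ECC-1 with BPA, median 0.02, and with genistein, median 0.35. The melanophilin gene MLPH was the member that rose in both, by 1.18 and 1.85 (1 and 2 adjusted over the list alone, adjusted p = 0.387 and adjusted p = 0.244 with an estimated correlation). The list call with BPA ended with trends removed (0.04) or both first estradiol libraries omitted (0.02). The MLPH call with BPA ended without the first DMSO (1.21), second DMSO (1.15) or first BPA (0.82) library. Steroid receptors and cofactors (14 measured) passed with estradiol in ECC-1, where PGR rose (2 adjusted over the list alone), median 0.20 (adjusted p = 0.00235, but adjusted p = 0.342 with an estimated correlation). With both first estradiol libraries omitted the median was 0.05 and the call ended. With BPA in ECC-1 their median of -0.02 and mean of 0.08 differed in sign.

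The lists that follow passed camera in none of the 6 treatment comparisons. Median changes ranged over the 6 from -0.02 to 0.06 for aryl hydrocarbon receptor targets (6 measured, CYP1A1 among them), from -0.05 to 0.12 for NRF2 targets (10), from -0.13 to 0.20 for unfolded protein and amino acid stress genes (12), from -0.16 to 0.03 for sterol synthesis genes (15), from -0.10 to 0.08 for glucocorticoid and progesterone receptor targets (9), from -0.11 to 0.06 for apoptosis regulators (12) and from -0.21 to 0.00 for replication-dependent histones (10). Endometrial markers (8) ranged from 0.00 to 0.14 and fibroblast markers (3) from -0.19 to 0.07. Medians and means differed in sign in several of these, for example for glucocorticoid and progesterone receptor targets with estradiol in ECC-1 (0.08 and -0.09). Leukocyte markers (2 measured, at most 6.31 scaled RPKM in any library) and endothelial markers (1 measured, at most 1.75) were too few to test. Collagen gene COL1A1 stood at 18.2 ± 0.209 in T-47D and 12.5 ± 3.61 in ECC-1 in DMSO (SD, n = 2). Within NRF2 targets the thioredoxin reductase gene TXNRD1 was lower with estradiol in T-47D (-0.87, adjusted p = 0.00227), a call that ended without the second DMSO library (-0.73). Another member, OSGIN1, was higher (0.97, adjusted p = 0.0193), a call that ended without the first DMSO (0.99), second DMSO (0.95) or first estradiol (0.79) library.

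A further hypothesis was that genes raised by estradiol in a single line may be silent in the other. Of the 196 genes raised in ECC-1, 27 of them in both lines, 47 (24%) stayed under 1 scaled RPKM in all 8 T-47D libraries. The median over 10000 random lists matched for level was 10.7% (middle 95% 6.63 to 14.8%). Of the 291 raised in T-47D, 83 (28.5%) stayed under 1 in all 8 ECC-1 libraries, against 11.7% (8.59 to 15.1%). A level under 1 is low rather than absent. PGR, at most 0.781 in ECC-1, lay under 1 there and still rose with estradiol. A low level in the other line thus goes with part of the difference, while most raised genes reached 1 scaled RPKM in both lines.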
